A study of Homo sapiens with 12 samples.

How the data were processed

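Nascent RNA libraries came from U2OS cells with a Per2 luciferase reporter, treated with 10 µM DRB or with DMSO for 1, 2 or 4 h from the peak or the trough of the reporter. Per the labels' protocols, RNA was labelled with 250 µM bromouridine for 0.5 h and captured with an antibody against it. Samples were placed in 4 groups of 3 from the labels, as peak or trough and DMSO or DRB. Replicates 1, 2 and 3 of a group name the libraries of 1, 2 and 4 h and are not repeats of one condition.

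Per the submitters' processing notes, reads were aligned with TopHat2 2.0.10 to hg19; the counting tool and whether it used strand are not given in the sources used here. The authors deposited 1 table of the whole series, with 13718 genes and 12 columns, all of which matched a sample in the labels. Its name speaks of FPKM, but the deposited values are a signal that the files show to be read coverage per gene length, without scaling for depth. For all 13718 genes, the 12 values were whole multiples of 100 kb divided by a whole-number length common to all libraries, within a tolerance of 0.01 reads and at most 5.83e-05 reads away. The recovered reads summed to between 21319973 and 27445556 per library, and these totals cover the listed genes, not the whole library. The recovered length had a median ratio of 1.00 to the summed intron length for 11498 annotated genes with introns, within 5% for 68.8% of them, and for 65.8% of 1288 genes without introns it was within 5% of the exonic length. The values are thus read densities that lie mostly over introns. The design had assumed FPKM, which are scaled for depth, so a scaling was added after the file was seen: each value was divided by the library's recovered total over the mean total.

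Gene names were used as the file gives them. Lengths and overlaps came from GENCODE v29 on GRCh38, with older symbols from RefSeq on GRCh38.p14, and 12786 genes (93.2%) matched, of which 1019 matched by an older symbol. No coordinates are printed, since the assembly differs from that of the files. Among the listed genes 137 shared all 12 values with another gene, and fits without them are among the alternatives. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom over genes ran from 13.5 to 119.

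Scaled values were tested as log2(value + 1), among genes with a mean of at least 1, a filter that removed no gene. Fold changes are on that scale. limma 3.58.1 in R 4.3.3 was used with an intensity trend, and adjusted p-values are Benjamini-Hochberg over 13718 genes, called under 0.05. The fit held 4 group means and time as a factor; DRB effects per time came from a fit with phase, time and treatment by time, and slopes from a fit with treatment, phase and log2 hours by phase. All 12 libraries shared 1 estimate of the spread. Gene lists, 27 in all and 22 with at least 5 measured genes, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Medians of lists were set against 10000 random lists matched in 10 bins of density by 5 bins of counted length. Slopes on length and shares of the 10 densest genes were compared over 6 matched pairs with exact sign-flip tests, which take the pairs as independent, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

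The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule took, for DRB over both phases, the 12 largest rises and 12 largest falls with an adjusted p under 0.05 and the same direction in all 6 pairs, and for the phases in DMSO the 6 largest each way with groups that did not overlap. Small RNA genes were counted and not named. They were told by name (MIR, SNORD, SNORA, RNU, RNY, VTRNA and SNAR genes) in place of by length, a choice made after values were seen that left the 24 genes named under DRB and the 12 named between phases as they were. Vault RNA VTRNA1-3 is given as a list member, and MIR197, SNORD41 and, as a densest gene, MIR3687 are named as exceptions, chosen after their values were seen. Small Cajal body RNA genes (SCARNA) were not among the names left out. Where fewer than 5 genes passed, the 5 with the smallest p each way were named with values. Every measured core clock gene was named between the phases, and up to 4 genes with the smallest p in other lists. Some members of the cholesterol synthesis and interferon lists are not reported here.

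Pairs of DRB and DMSO libraries share phase and time in the labels. Their deviations from the group means correlated between 0.126 and 0.298 across genes, over 0.1 in all 6 pairs, and each DRB library correlated best with its own DMSO library in 6 of 6 cases. The pairs were therefore read as paired. The planned fit without a block stayed the main one, and counts with the pair as a block are given beside it. Peak and trough libraries of the same treatment and hour also share a number. In DRB their deviations correlated between 0.391 and 0.626, over 0.1 in all 3 pairs, so these were read as paired too. In DMSO the correlations ran from 0.0414 to 0.227, so there the number was not read as a pairing. All these deviations still held the effect of time. A change with hours that libraries share can thus give such correlations without a shared culture or batch, and these were not told apart. Data were simulated for 13718 genes with the real means and spread of each gene. Changes of 1.25-fold, 1.5-fold, 2-fold and 3-fold between DRB and DMSO were recovered for 20%, 60%, 96% and 98% of the changed genes. With them 7 unchanged genes were called. The changed genes were not drawn from those with the fewest reads. For the peak against the trough in DMSO the shares were 10%, 36%, 86% and 98%, with 10 unchanged genes called. A list shifted by 0.5 was called, and 0 of 21 others were. Genes were simulated independently there, while the estimated correlation within real lists was up to 0.514, for p53 targets. The simulation therefore cannot tell how often real lists are called by chance. The simulated data also held no effect of time and no pairing of libraries.

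Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a mean of at least 5, median centring, quantile normalization, no intensity trend, the pair as a block, each library left out in turn, other set tests, exonic length, Spearman correlation, a detection level of 0.1 and the 100 densest genes. Added after seeing the data were no scaling for depth, a pseudocount of 500, at least 100 mean reads, no genes with shared values, recovered reads with voom weights, no 1 h libraries, the counted length and the share of reads.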

Results

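Nascent RNA was measured in U2OS cells, a human osteosarcoma line that carried a luciferase reporter driven by the promoter of the clock gene PER2. DRB, an inhibitor of the kinases that release RNA polymerase II into elongation, was given at 10 µM, and control cells received the solvent DMSO. Treatment began at the peak or at the trough of the reporter and lasted 1, 2 or 4 h. RNA made during 0.5 h of labelling with 250 µM bromouridine was captured with an antibody. The 12 libraries formed 4 groups of 3 (peak or trough, DMSO or DRB), and each group held 1 library at 1 h, 1 at 2 h and 1 at 4 h. No condition had a second library, so the spread within a group included the effect of time. Reads in the 13718 listed genes numbered from 21319973 to 27445556 per library, and the median gene had a mean of 731 reads. Values below are read densities, mostly over introns, in reads per 100 kb after scaling each library to the mean total. Nothing in the labels says that libraries came from separate cultures, so p-values measured the spread between these libraries, which may be technical. In the fit with group means and time, that spread also held any change with hours that differed between the groups.

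The series was made to learn how a low dose of DRB alters transcription across the genome. At this dose DRB shifted many of the 13718 listed genes modestly, in both directions. CDKN1A, the cell cycle inhibitor induced by p53, rose 2.31-fold, from 18783 ± 2286 to 43989 ± 9828 reads per 100 kb (SD, n = 6 libraries each). EGFR, the epidermal growth factor receptor, fell from 965 ± 137 to 224 ± 86.9 reads per 100 kb, a 4.62-fold fall. MALAT1, a nuclear long noncoding RNA, rose 1.56-fold. In the limma fit over both phases, 2714 genes were higher and 3067 lower at an adjusted p under 0.05, and the median size of a called change was 0.42 on the log2 scale. Changes beyond 2-fold were called for 53 higher and 251 lower genes. The fold changes are relative to the reads in the listed genes, so a change common to all genes could not be seen. Without any scaling for depth the counts were 1487 higher and 2093 lower. With each pair of phase and time as a block 4890 genes were called in place of 5781, and 4800 were called in the same direction by both fits.

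Among genes that moved the same way in all 6 matched pairs of phase and time, the 12 largest rises included TAS2R9 and TAS2R8, which encode bitter taste receptors, with log2 fold changes of 1.91 ± 0.35 (SE) and 1.24 ± 0.31. ABI3BP rose by 1.52 ± 0.17, the kinase gene YSK4 by 1.52 ± 0.15 and NFE2L3, a transcription factor of the NRF family, by 1.40 ± 0.14. DUSP1, a phosphatase that turns off MAP kinases, rose by 1.37 ± 0.15, from 11925 ± 2950 to 30644 ± 7086 reads per 100 kb. The remaining rises in this set were LOC100507634 (1.54 ± 0.21), CLGN (1.35 ± 0.22), the nucleoside transporter gene SLC28A2 (1.30 ± 0.11), BST1 (1.29 ± 0.18), the sulfotransferase gene CHST7 (1.26 ± 0.13) and C8orf75 (1.24 ± 0.17). The steepest fall was that of IL18R1, a subunit of the interleukin 18 receptor, at -2.48 ± 0.21, followed by EGFR at -2.21 ± 0.20. Genes for the receptor ADRA2C and the olfactory receptors OR2T8 and OR13G1 had changes of -2.04 ± 0.28, -2.09 ± 0.56 and -1.86 ± 0.43. SAMD5 fell by 1.93 ± 0.17, the potassium channel gene KCNG2 by 1.84 ± 0.22, PARP10 by 1.83 ± 0.28, FIBIN by 1.80 ± 0.30, FAM133A by 1.72 ± 0.24, C10orf113 by 1.71 ± 0.17 and the transcription factor gene POU3F3 by 1.68 ± 0.24. Adjusted p-values of these 24 genes ran from 0.000384 to 0.0165. Depth behind some was low; the mean was 8.33 reads for ADRA2C, 11 for OR2T8, 11.3 for OR13G1 and for FIBIN, 16.8 for TAS2R8 and 23.9 for TAS2R9. NFE2L3 overlaps HNRNPA2B1, IL18R1 overlaps IL1RL1, BST1 overlaps FAM200B, C10orf113 overlaps NEBL, and PARP10 overlaps GRINA and SPATC1, so reads of these pairs may be shared.

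**Figure D1:**
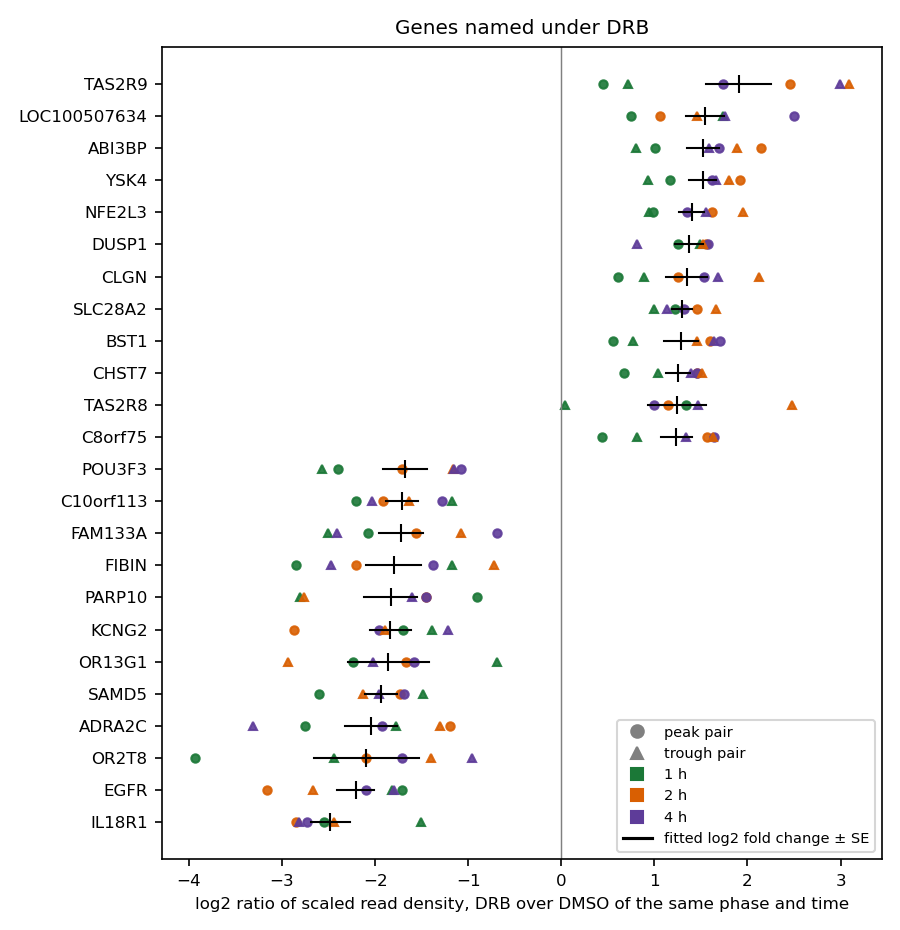
Log2 ratio of scaled read density, DRB over DMSO, for the 24 genes named by size under DRB; each point is 1 matched pair (circles peak, triangles trough; colours 1, 2 and 4 h), and the black mark is the fitted log2 fold change ± SE. All 6 points of each gene lie on one side of 0, from IL18R1 at -2.48 to TAS2R9 at 1.91.

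In 6 lists, from p53 targets to cholesterol synthesis, rises outnumbered falls, and their set tests gave an adjusted p of 0.274 to 0.322 with an estimated correlation. Of 23 measured p53 targets, 18 rose and 0 fell (18 and 0 adjusted over the list alone), among them CDKN1A (1.21 ± 0.10), TP53INP1 (0.69 ± 0.06), RRM2B (0.66 ± 0.07) and PHLDA3 (0.62 ± 0.09). Immediate early genes, which answer growth factors within minutes, gave 11 rises and 0 falls among 19 (12 and 0 adjusted over the list alone), among them CYR61 (1.07 ± 0.10), DUSP1, BTG2 (1.02 ± 0.15) and SRF (0.38 ± 0.06). For NF-kB targets and cytokines the numbers were 6 and 0 of 10 (6 and 1 adjusted over the list alone), with CCL2 at 0.91 ± 0.09 and NFKBIZ at 0.57 ± 0.07. Heat shock and proteostasis genes gave 11 and 0 of 14 (11 and 0 adjusted over the list alone), with DNAJB1 at 0.89 ± 0.11 and HSP90AB1 at 0.68 ± 0.07. In the list of ATF4 and the unfolded protein response, 9 of 16 rose and 0 fell (10 and 0 adjusted over the list alone), with HSPA5 at 0.68 ± 0.06 and XBP1 at 0.55 ± 0.06. Cholesterol synthesis genes gave 16 rises and 0 falls among 19 (16 and 0 adjusted over the list alone), with IDI1 at 0.50 ± 0.06 and CYP51A1, a sterol demethylase, at 0.54 ± 0.06.

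Genes for cytosolic ribosomal proteins gave 29 rises and 0 falls among 36 (31 and 1 adjusted over the list alone), with RPS20 at 0.79 ± 0.07 and RPL19 at 0.57 ± 0.06. Cell cycle genes gave 16 and 1 of 23 (17 and 1 adjusted over the list alone); PCNA, the sliding clamp of DNA replication, rose by 0.63 ± 0.09 and E2F1 fell by 0.47 ± 0.08. Splicing factors gave 15 and 1 of 25 (16 and 2 adjusted over the list alone), with HNRNPA2B1 at 0.51 ± 0.06 and HNRNPC at 0.42 ± 0.06. Nuclear long noncoding RNAs and snoRNA hosts gave 6 and 0 of 15 (10 and 0 adjusted over the list alone), with MALAT1 at 0.64 ± 0.09 and NEAT1 at 0.63 ± 0.08. Replication-dependent histone genes split, with 5 rises and 1 fall among 20 (5 and 1 adjusted over the list alone): HIST1H2BD rose by 1.20 ± 0.10 and HIST1H3H by 1.21 ± 0.16, while HIST4H4 fell by 0.52 ± 0.12. Of the targets of TGF-beta, SRF and YAP, 10 rose and 1 fell among 19 (10 and 1 adjusted over the list alone); the fall was SMAD6, an inhibitor of BMP signalling, at -1.35 ± 0.10.

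Genes of the machinery that DRB acts on moved both ways. Among 26 genes of P-TEFb, 7SK and elongation, 12 rose and 6 fell (12 and 6 adjusted over the list alone): CDK9, a kinase that DRB inhibits, rose by 0.62 ± 0.07 and its partner CCNT1 by 0.55 ± 0.06, while CDK12 fell by 0.41 ± 0.06 and AFF1 by 0.40 ± 0.07. The list of CDK7 and general initiation gave 5 and 4 of 19 (5 and 5 adjusted over the list alone), with TBP at 0.47 ± 0.06 and CDK8 at -0.33 ± 0.07. Clock and casein kinases gave 4 and 0 of 13 (3 and 0 adjusted over the list alone), with CSNK1A1 at 0.33 ± 0.05. Hypoxia and glycolysis genes divided 7 to 6 among 16 (7 and 6 adjusted over the list alone): the glycolytic genes GAPDH and ALDOA rose by 0.55 ± 0.07 and 0.43 ± 0.06, and NDRG1 and PFKFB4 fell by 0.95 ± 0.12 and 0.69 ± 0.09. The interferon list gave 1 rise and 4 falls among 7 (1 and 4 adjusted over the list alone), with USP18 at -0.95 ± 0.14. Krueppel-type zinc finger genes gave 6 and 5 of 26 (6 and 5 adjusted over the list alone), with ZNF121 at 0.55 ± 0.06 and ZNF10 at -0.94 ± 0.17. Matrix and osteoblast genes gave 1 and 2 of 11 (1 and 2 adjusted over the list alone), with COL5A2 at -0.68 ± 0.10.

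Clock genes gave more rises than falls. Of 18 core clock genes, 7 rose and 2 fell (9 and 3 adjusted over the list alone). The E-box and D-box output list, which overlaps the core list, gave 8 rises and 2 falls among 16 (11 and 2 adjusted over the list alone). At its preset correlation camera did not call the core list (adjusted p = 0.0923) and called the output list (adjusted p = 0.00491). With an estimated correlation it called neither (adjusted p = 0.322 and 0.294), while fry called both (adjusted p = 0.00985 and 0.00206). BHLHE40 rose by 0.89 ± 0.13, the repressor gene NR1D1 by 0.73 ± 0.06, DBP by 0.72 ± 0.13, PER1 by 0.66 ± 0.14 and PER2 by 0.41 ± 0.10. ARNTL2 and NPAS2, which encode activators of the clock, fell by 0.55 ± 0.07 and 0.44 ± 0.10. The activator gene ARNTL had -0.25 ± 0.15, CLOCK -0.03 ± 0.06 and the repressor gene CRY1 -0.37 ± 0.13, and none of these passed the test.

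With camera and a preset correlation of 0.01, 14 of 22 lists stood above the other genes and 0 below. None of the 14 held with an estimated correlation, where their adjusted p ran from 0.274 to 0.43. fry, which does not set a list against the other genes, called 18 of 22. With quantile normalization 9 of the lists were called, and the calls of P-TEFb and elongation, histones, nuclear long noncoding RNAs, splicing factors and the targets of TGF-beta, SRF and YAP ended. Their medians went from 0.19 to 0.21, from 0.25 to 0.11, from 0.27 to 0.12, from 0.26 to 0.13 and from 0.32 to 0.25, in that order. For hypoxia and glycolysis genes the median (0.13) and the mean (-0.10) differed in sign. Most lists were denser in reads than the median gene, and dense genes lay higher under DRB, so each list was also set against 10000 random lists matched on read density and length. The medians of p53 targets (0.49 against a matched 0.15) and cholesterol synthesis genes (0.43 against 0.17) lay above every matched list, at percentile 100. Those of ribosomal proteins, immediate early genes and clock outputs lay at percentiles 99.97, 99.95 and 99.51. Splicing factors, at percentile 87.5, and histones, at percentile 93.8, lay within the range of matched lists. A wider set of 53 histone genes, taken by name after values were seen, lay at percentile 99.86, with a median of 0.25, 18 rises and 2 falls.

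**Figure D2:**
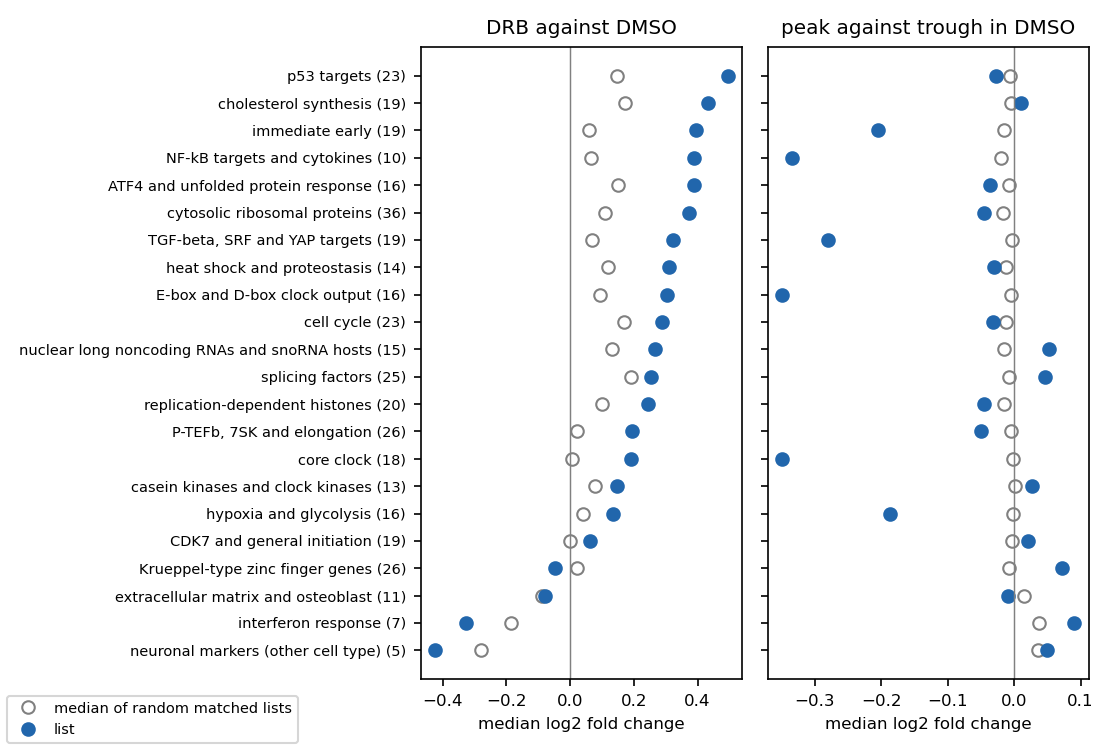
Median log2 fold change of each tested list (filled) and the median of random lists matched on read density and length (open), with the number of measured genes in brackets, for DRB against DMSO (left) and the reporter peak against its trough in DMSO (right). Under DRB p53 targets lie at 0.49 against a matched 0.15, and between phases core clock genes lie at -0.35 against a matched value of -0.00199.

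Markers of other cell types were few. Of 13 neuronal markers 5 were measured, and 3 fell (4 adjusted over the list alone): GAD1 at -0.70 ± 0.17, RBFOX3 at -0.46 ± 0.12 and MAP2 at -0.42 ± 0.12. Quantile normalization turned GAD1 to 0.07, RBFOX3 to 0.29 and the median of the list from -0.42 to 0.07. Of the haematopoietic, epithelial and hepatocyte markers 1, 2 and 1 were measured, which was too few to test: CD4 at -0.57 ± 0.19, KRT18 at 0.68 ± 0.12, CLDN4 at -0.47 ± 0.15 and SERPINA1 at -0.05 ± 0.21. No mitochondrially encoded gene was among the listed genes, and of the fixed list of products of RNA polymerases I and III BCYRN1, RMRP, RPPH1 and VTRNA1-3 were measured, with changes of 0.15 ± 0.05, -0.41 ± 0.20, 0.09 ± 0.20 and 0.06 ± 0.18.

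The labels split the libraries by phase, so the DRB effect was compared between phases. CDKN1A rose in both, by 1.32 ± 0.14 at the peak and 1.09 ± 0.14 at the trough on the log2 scale. EGFR fell in both, with changes of -2.32 ± 0.28 and -2.09 ± 0.28. At the peak 1335 genes were higher and 1623 lower, and at the trough 1514 and 1400. Leaving out 1 library took the first count as low as 805 (without the DMSO library of 2 h) and the second as low as 578 (without the DRB library of 2 h). Of the called genes, 1046 were higher and 1135 lower in both phases, against 147 and 166 expected of independent lists, and 3 went opposite ways. The fold changes correlated across genes with r = 0.80; genes are not independent replicates. DRB libraries of the same hour deviated together across the phases, by shared error or by a shared change with hours. These were not told apart, so part of this overlap may come from shared error. CDKN1A differed between the phases by 0.24 and EGFR by -0.23 on the log2 scale, each with an adjusted p of 1. The test of the difference called 0 genes in limma, with 186 at an unadjusted p under 0.05, and 0 in a fit of recovered reads with voom weights. The smallest adjusted p, 0.159, belonged to the small nucleolar RNA gene SNORD41 (3.02 ± 0.34) and the next, 0.31, to MIR197 (1.34 ± 0.18), both named after their values were seen. MIR197 rests on a mean of 23.8 reads. With the small RNA genes left out by name, the 5 genes with the smallest p in each direction had differences of 2.72 ± 0.48 (C5orf39), 1.11 ± 0.21 (FLJ30679), 3.14 ± 0.79 (OR1Q1), 0.96 ± 0.26 (SCARNA10) and 0.64 ± 0.18 (C9orf78), and of -0.74 ± 0.17 (RBM43), -1.01 ± 0.27 (DBNDD2), -0.64 ± 0.18 (C8orf40), -0.92 ± 0.26 (SCARNA17) and -0.94 ± 0.27 (PNPLA1), each with an adjusted p of 1. SCARNA10 and SCARNA17 are small Cajal body RNA genes, which that choice of names did not cover. With each pair of phase and time as a block, 1787 genes were called at the peak and 1758 at the trough, in place of 2958 and 2914. Without scaling for depth the share of higher genes at the peak was 16.2%, in place of 45.1%.

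The DRB effect was also compared between hours. Each hour was 1 set of libraries, and its DRB libraries deviated together, so the duration of treatment was not separated from differences between those sets. ABI3BP was 0.90 higher on the log2 scale at 1 h and 1.64 higher at 4 h, a difference of 0.74 ± 0.16 that passed the test (adjusted p = 0.0269). BST1 went from 0.66 to 1.67 and C8orf75 from 0.63 to 1.49. POU3F3 was 2.48 lower at 1 h and 1.11 lower at 4 h. Of the 23 p53 targets 8 were higher and 4 lower under DRB at 1 h (8 and 4 adjusted over the list alone), against 19 and 0 at 4 h (21 and 0 adjusted over the list alone). By the test of the difference 5 lay higher at 4 h than at 1 h (5 adjusted over the list alone), with differences of 1.15 ± 0.11 for FDXR, 0.68 ± 0.14 for TP53I3, 0.71 ± 0.16 for FAS and 0.51 ± 0.11 for XPC. FDXR, a mitochondrial electron carrier, fell by 0.36 at 1 h and rose by 0.80 at 4 h. camera set this list and the Krueppel-type zinc finger genes above the other genes, and ribosomal proteins, histones, cell cycle genes and matrix and osteoblast genes below them (adjusted p = 0.808 with an estimated correlation for each). Of 26 Krueppel-type zinc finger genes 5 were higher and 15 lower at 1 h (5 and 15 adjusted over the list alone), against 5 and 1 at 4 h (5 and 1 adjusted over the list alone). By the test of the difference 10 lay higher at 4 h and 0 lower (11 and 0 adjusted over the list alone), with ZNF45 at 0.96 ± 0.13 and ZNF37A at 0.60 ± 0.08. Their median of 0.37 lay within the range of matched lists, at percentile 75.2, and dropped to 0.10 with median centring and 0.12 with quantile normalization; all 408 zinc finger genes lay at percentile 22.1. In the 4 lists set below, HIST1H1E (-0.70 ± 0.13) and CCNA2 (-0.61 ± 0.17) passed, and of these HIST1H1E passed adjusted over the list alone. The medians of those 4 lists lay between -0.12 and -0.03, and without scaling for depth they turned to between 0.11 and 0.20. In all, 1346 genes were higher and 4186 lower at 1 h, 2457 and 2318 at 2 h, and 2171 and 1656 at 4 h. Between 4 h and 1 h the DRB effect was higher for 1877 genes and lower for 406.

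These splits by time rested on the scaling. Median centring moved the median of all genes by 0.18 on the log2 scale at 1 h, and by -0.27 for 4 h against 1 h. With it the share of higher genes was 53.2% at 1 h, in place of 24.3%, and 34.2% at 4 h, in place of 56.7%. For the difference of 4 h and 1 h the share fell from 82.2% to 26.7% with median centring and 27.4% with quantile normalization, and was 97.3% unscaled. At 2 h the unscaled share was 22.8%, in place of 51.5%. The number of genes that differed between 4 h and 1 h was 0 without the DMSO library of 1 h at the peak, and again 0 without that of the trough. With 1 library left out the calls were as few as 2778 at 1 h (without the trough DMSO library of 1 h), 1647 at 2 h (without the trough DRB library of 2 h) and 1265 at 4 h (without the peak DRB library of 4 h). The p53 median for the difference of 4 h and 1 h was 0.49, at percentile 100 of matched lists, and stayed above 0 with median centring (0.22) and quantile normalization (0.29).

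The response to DRB was also set against gene length at each hour. At 1 h genes over 300 kb lay 0.26 above the median of all genes, and at 4 h they lay 0.44 below it. Genes of 3 to 10 kb lay 0.17 above it at 1 h, 0.19 at 2 h and 0.22 at 4 h. The slope of the log2 ratio on log10 length, over 12786 genes with an annotated length, was 0.03 at the peak and -0.03 at the trough at 1 h, and -0.15 and -0.12 at 4 h. Over the 6 pairs it was -0.08 ± 0.07 (SD), negative in 5, with an exact two-sided sign-flip p of 0.0938, where 0.0312 was the smallest possible. The slope dropped by 0.07 per doubling of hours (exact two-sided permutation p = 0.0222 over 90 arrangements, the smallest they can give). That p takes the 6 pairs as independent and is too small, since the DRB libraries of an hour deviated together. Between peak and trough in DMSO, where no drug was given, slopes lay between -0.01 and 0.04.

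**Figure D3:**
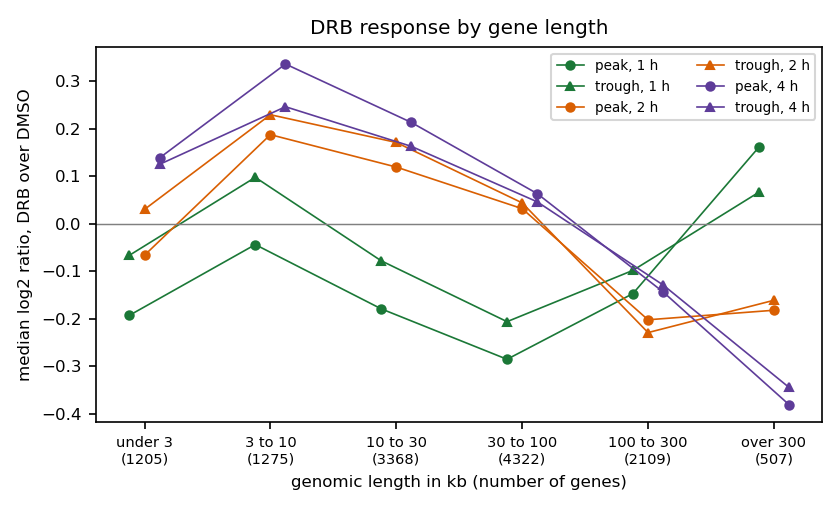
Median log2 ratio of read density, DRB over DMSO, by class of genomic length in kb (number of genes in brackets) for each of the 6 matched pairs (circles peak, triangles trough; colours 1, 2 and 4 h). Genes over 300 kb lie above 0 in both pairs of 1 h and at -0.38 and -0.34 in those of 4 h.

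The phase of the reporter was the other axis of the design. In DMSO, NR1D1 stood at 6097 ± 312 reads per 100 kb at the peak and 15469 ± 2317 at the trough (SD, n = 3), a log2 difference of -1.33 ± 0.08 (adjusted p = 0.00117). WNT11, a secreted signalling protein, was higher at the peak, at 1299 ± 24.3 against 340 ± 72.4. TIMP3, an inhibitor of matrix proteases, was lower at the peak, at 1986 ± 189 against 3897 ± 182. limma called 7 genes higher and 11 lower at the peak. The largest with groups that did not overlap, which chance gives for 10% of genes, were, on the higher side, WNT11 (1.95 ± 0.15), LOC286094 (1.59 ± 0.17), FAM13C (1.48 ± 0.19), TET1, which oxidises methylated cytosine (0.91 ± 0.12), RASL11B (0.80 ± 0.11) and DNAJC15 (0.77 ± 0.10). On the lower side they were C10orf55 (-1.55 ± 0.19), LOC152225 (-1.54 ± 0.21), NR1D1, the hepatic lipase gene LIPC (-1.19 ± 0.13), the interleukin 1 receptor subunit gene IL1RAP (-1.16 ± 0.14) and TIMP3 (-0.98 ± 0.10). C10orf55 overlaps PLAU, NR1D1 overlaps THRA, LIPC overlaps ALDH1A2, TIMP3 overlaps SYN3 and FAM13C overlaps PHYHIPL.

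The phase difference was also tested in the DRB libraries. These deviated together with the DMSO libraries of the same phase and time, so part of the overlap may come from shared error. Of the 18 called genes 17 were called in the same direction under DRB. MIR197 was the exception, at -0.96 ± 0.13 in DMSO and 0.38 ± 0.13 in DRB, where it was not called. It rests on a mean of 23.8 reads, so no reversal is read from it. In the DRB libraries 43 genes were higher and 65 lower at the peak, with NR1D1 at -1.25 ± 0.08 and WNT11 at 2.17 ± 0.15. With peak and trough libraries of the same hour as a block the numbers in DRB were 132 and 209, and 102 of the 108 genes were among them in the same direction. The fold changes of both treatments correlated across genes with r = 0.55. The count in DMSO was unstable: it was 0 without both peak libraries of 1 h or without the 4 libraries of 1 h, 86 among genes with at least 100 reads, and 183 with voom weights. With any 1 library left out it ranged from 2 to 28. The count in DRB was 6 and 0 without those libraries, 230 with at least 100 reads and 348 with voom weights, and with 1 library left out it ranged from 4, without the trough DRB library of 2 h, to 174, without the peak DRB library of 4 h. Without scaling for depth the shares of higher genes were 20.8% in DMSO and 20.0% in DRB, in place of 38.9% and 39.8%.

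**Figure D4:**
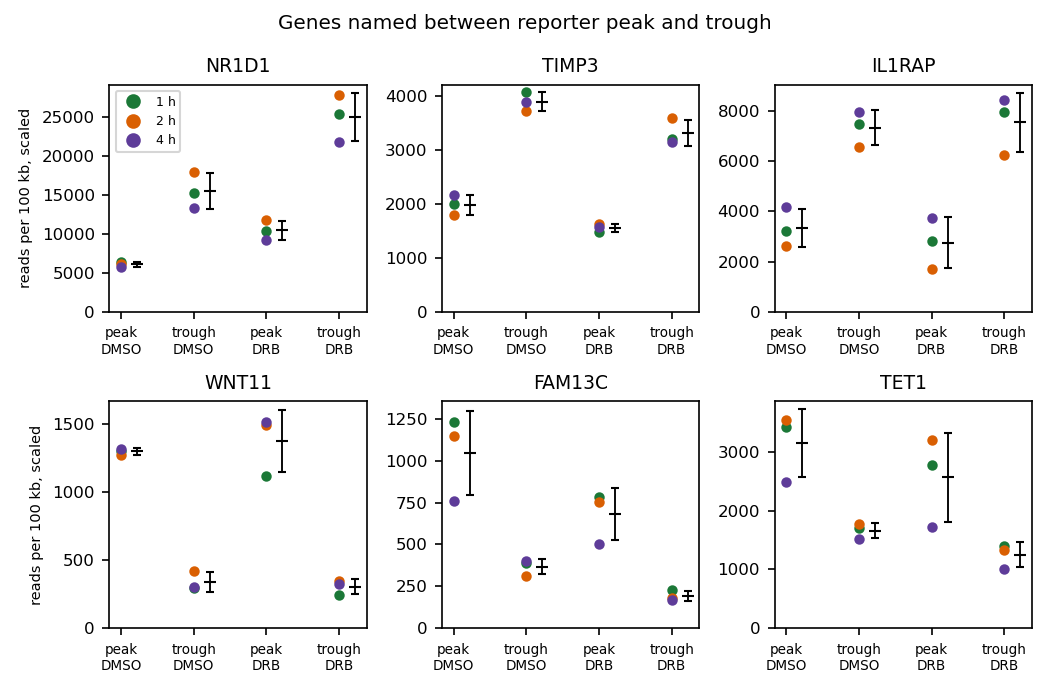
Scaled read density (reads per 100 kb) of 6 genes named between phases, per library (points, coloured by hours of treatment) with the mean ± SD of each group of 3. NR1D1 lies at 6097 ± 312 at the peak and 15469 ± 2317 at the trough in DMSO, and WNT11 at 1299 ± 24.3 and 340 ± 72.4.

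The median of the 18 core clock genes was -0.35 at the peak against the trough (adjusted p = 0.0893 with an estimated correlation). Of the 18 core clock genes 1 passed the test over all genes, and 8 were lower and 0 higher adjusted over the list alone. NR1D2 had a difference of -0.59 ± 0.13, DBP of -0.77 ± 0.18, PER1 of -0.87 ± 0.21, PER2 of -0.47 ± 0.14, PER3 of -0.31 ± 0.15 and CRY2 of -0.39 ± 0.12. The values were -0.68 ± 0.14 for NPAS2, -0.78 ± 0.20 for HLF, -0.42 ± 0.18 for BHLHE40, -0.24 ± 0.16 for TEF, -0.11 ± 0.19 for CRY1 and -0.09 ± 0.19 for BHLHE41. ARNTL, which encodes the clock activator BMAL1, had 0.27 ± 0.21, RORA 0.21 ± 0.10, NFIL3 0.02 ± 0.13, CLOCK -0.06 ± 0.09 and ARNTL2 -0.07 ± 0.09. Over the output list the numbers were 1 lower over all genes and 7 lower and 0 higher adjusted over the list alone.

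camera set 6 lists below the other genes at the peak: core clock and clock output (medians -0.35 each), NF-kB targets (-0.33), targets of TGF-beta, SRF and YAP (-0.28), immediate early genes (-0.20) and hypoxia and glycolysis (-0.19). Adjusted p-values with an estimated correlation ran from 0.0893, for both clock lists, to 0.775, so no call held there. fry called the core clock and clock output lists (adjusted p = 0.00516 each) and none of the others. The medians of these clock lists lay at percentile 0 of matched lists. In the last 4 lists 0 genes passed over all genes, and 4, 2, 1 and 2 were lower adjusted over the list alone. The smallest p belonged to HK2 (-0.79 ± 0.12), which starts glycolysis, CTGF (-0.86 ± 0.16) and RELB (-0.54 ± 0.12). camera called none of the other 16 tested lists, and 0 of their genes passed over all genes.

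Time after the peak or the trough was compared as a slope per doubling of hours. limma called 0 genes that differed in slope between the phases, with 460 at an unadjusted p under 0.05, and voom weights gave 0. With the same small RNA genes left out, the smallest p on the positive side belonged to ARNTL (0.49 ± 0.08), SERPINA1 (0.66 ± 0.12), RGS16 (0.48 ± 0.11), LDOC1 (0.43 ± 0.10) and ITGB3 (0.48 ± 0.11). On the negative side it belonged to MRPS30 (-0.40 ± 0.09), TMEM218 (-0.35 ± 0.08), SNRPD2 (-0.33 ± 0.08), POLR3GL (-0.40 ± 0.10) and MS4A15 (-1.08 ± 0.27), and the adjusted p was 1 for each of the 10. Of the lists, camera set 5 above and 1 below the other genes, with the smallest camera p for ATF4 and the unfolded protein response, at 0.21 per doubling with 0 genes past the threshold over all genes and 4 higher adjusted over the list alone. Immediate early genes had a larger median, 0.29, with 0 genes past the threshold over all genes or adjusted over the list alone. The adjusted p of these 6 lists with an estimated correlation ran from 0.346 to 0.89.

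The 10 densest genes held between 29.8% and 41.1% of the summed density of a library, and MIR3687 or MTRNR2L2 was the densest in each. This share was 35.2% in DMSO and 36.1% in DRB, higher under DRB in 3 of 6 pairs, with a difference of 0.85 ± 4.33 percentage points (SD, exact two-sided sign-flip p = 0.688). As a share of reads, the 10 genes with most reads held 3.04% in DMSO and 3.58% in DRB, higher in 6 of 6 pairs (exact two-sided sign-flip p = 0.0312, the smallest possible). All genes had a scaled density of at least 1 in all libraries, so the number of detected genes could not differ.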

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

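Tests chosen only after the result was seen were the comparison of the length trend between phases and the other splits of the libraries for counts under DRB and between phases. The effect of DRB differed between 4 h and 1 h for 2283 genes by the test of the difference itself. Of the genes named under DRB, 5 were among them, with log2 differences of 1.78 ± 0.48 for TAS2R9, 0.74 ± 0.16 for ABI3BP, 1.01 ± 0.24 for BST1, 0.86 ± 0.20 for C8orf75 and 1.37 ± 0.35 for POU3F3 (limma, adjusted p between 0.0269 and 0.046). For the first 4 the rise was larger at 4 h, and for POU3F3 the fall was smaller. Without the peak or the trough DMSO library of 1 h the count of differing genes was 0, and TAS2R9 rests on a mean of 23.9 reads.

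The 5 lists weighed against read density and length were p53 targets, immediate early genes, clock outputs, ribosomal proteins and cholesterol synthesis genes, which camera set above other genes under DRB at its preset correlation (adjusted p between 0.294 and 0.304 with an estimated correlation). If density and length were the whole cause, the median of a list would lie within the range of random lists matched on both. The percentiles were 100 for p53 targets and for cholesterol synthesis, 99.95 for immediate early genes, 99.51 for clock outputs and 99.97 for ribosomal proteins, all past the bound of 99 set beforehand, which argues against it. Genes of a list can still move together by chance: of 100 splits of the 12 libraries, 8 gave as many lists as the real split (14, and 14 in the highest other), and of 32 splits that swapped labels within matched pairs 4 did (16 in the highest other), so chance was not excluded for the number of lists. A response of these pathways to DRB stays open as a hypothesis.

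Genes of low read density lay lower under DRB than dense ones. Between the sparsest and the densest of 3 equal classes the difference was -0.42 ± 0.06 on the log2 scale (SD, 6 of 6 pairs). Counting noise and gene length are argued against, since it was -0.34 among genes with at least 1000 reads and -0.23 in the class of counted length where it was smallest, of 3, each negative in 6 of 6 pairs. Fewer background reads in the DRB libraries were weighed with the 83 olfactory receptor genes, which this cell line has little reason to transcribe. Their median was -0.34 against -0.22 in lists matched on density, at percentile 0.75. Matched on length too it lay at percentile 1.58. This test cannot decide the question, since sparse genes were already known to lie below 0 and the bound set beforehand could hardly be missed. These genes also rest on a median of 13.7 mean reads, so a part from background stays open. A drug effect on weakly transcribed genes was not separately tested and stays open.

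The slope of the DRB response on gene length fell from 1 h to 4 h by 0.14 per log10 unit of length. Read density cannot be told apart from length as a cause, because the change was -0.46 in the sparsest of 3 density classes, -0.19 in the middle and -0.0507 in the densest. Whether a single pair of libraries was the cause could not be told. The change was -0.18 at the peak and -0.0907 at the trough, negative in both and from different pairs. DRB libraries of the same hour deviated together, so these changes are not independent. The smaller lay just under the bound set for it after the result was seen, so by that bound a large part from a single pair was not excluded. Slower progress of polymerase through long genes under DRB was not tested, and no value here separates it from density. Genes over 300 kb lay 0.26 above the median of all genes at 1 h and 0.44 below it at 4 h, so such an account would have to cover both.

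For the number of genes that differed between DRB and DMSO, 1 of 100 splits of the 12 libraries, the real one, gave as many (5781, against 2 in the highest other). Among 32 splits that swapped labels within matched pairs the highest other gave 0. These splits take libraries or pairs as independent, but DRB libraries of the same hour deviated together. Swaps of whole hours would be too few for a share under 0.05, so chance is argued against and not excluded. A real DRB effect also adds to the spread in every other split, which lowers their counts. The comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. There the real split gave 2958 genes at the peak, 2914 at the trough, 18 between phases in DMSO and 108 in DRB, the highest other split gave 0 in each, and 1 of 10 splits was as large. For the difference of the DRB effect between phases and for time slopes the real count was 0 (highest other 0 and 1), which all 10 and all 100 splits equal or exceed by construction, so these splits test nothing. For the lists between phases 7 of 10 splits gave as many as the real 6, with 8 in the highest other.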

How the results depend on the processing

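Alternatives chosen after seeing the data were no scaling for depth, a pseudocount of 500, at least 100 mean reads, no genes with shared values, voom weights, fits without libraries of 1 h, the counted length and the share of reads; the others were planned. The 24 genes named by size under DRB kept their direction and call under every alternative in which they were tested, single libraries left out included. They were chosen for a call, a large change and the same direction in every matched pair, so a kept direction largely follows from that choice. ADRA2C, OR2T8, OR13G1, FIBIN, TAS2R8 and TAS2R9 have under 100 mean reads. The fit with at least 100 mean reads left them out, so it does not test them. Of 257 called genes named or listed in the DRB comparison, 205 kept the call with each library left out. Between phases 2 of 12 did, NR1D1 and WNT11, and both ended without the peak libraries of 1 h (adjusted p = 0.0604 and 0.0674) or without all of 1 h (0.136 and 0.15), where fewer libraries were left. At 2 and 4 h in DMSO, NR1D1 lay at 6107 and 5780 reads per 100 kb at the peak against 17926 and 13324 at the trough. WNT11 lay at 1273 and 1320 against 423 and 302. A pseudocount of 0.1 is small beside the densities, and no filter or a mean of at least 5 removed no gene, so these say nothing of stability. The cause of the changes below was not tested unless given.

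Median centring called 28 genes between phases in DMSO and 1149 between 4 h and 1 h. Quantile normalization called 94 and 700, with 2250 at 4 h and 9 lists under DRB, and it turned RBFOX3 to 0.29 and GAD1 to 0.0746. No scaling called 3580 genes over both phases, 937 at the peak, 706 at the trough, 1 for the difference between phases, 60 between phases in DRB, 2030 at 2 h and 2338 at 4 h. At least 100 mean reads left 12359 genes and called 86 between phases in DMSO and 230 in DRB, and voom weights called 183 and 348. An estimated correlation ended the calls of all lists (0 under DRB, 0 between phases). fry called 18 under DRB and 2 between phases, core clock and clock outputs. Rank correlation with length was -0.22 and the share of reads in 10 genes rose by 0.54 points, each with the smallest exact p its test can give, 0.0312.

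With pairs of phase and time as a replicate block the counts were 1787 at the peak and 1758 at the trough, of which 1720 and 1696 were called in the same direction without it. Over both phases the block gave 4890 genes, of which 4800 were called in the same direction without it. By hour it gave 5894 at 1 h, 5204 at 2 h, 4145 at 4 h and 2625 between 4 h and 1 h. No count under DRB but those at the peak and the trough moved by over 1.5 times. With peak and trough libraries of the same hour as a replicate block the count in DRB was 341. In DMSO, where these libraries share a number only (correlations from 0.0414 to 0.227, each best with its own number in 3 of 3), that block gave 17 genes, of which 9 were among the 18 called without it. Of the 34 genes named or listed between phases 26 kept their side of the threshold, 7 no longer passed it and 1, PER1, newly did (adjusted p = 0.0352).

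Without both peak libraries of 1 h the counts were 1004 at the peak, 0 between phases in DMSO and 6 in DRB; without all 4 libraries of 1 h they were 1598 at the peak, 1537 at the trough, 0 and 0. Fewer libraries and residual degrees of freedom are part of this by construction. With 1 library left out in turn, the ranges were 4340 to 5613 over both phases, 805 to 2946 at the peak, 578 to 3333 at the trough, 0 to 1 for their difference, 2 to 28 between phases in DMSO, 4 to 174 in DRB, 2778 to 5399 at 1 h, 1647 to 4773 at 2 h, 1265 to 3808 at 4 h, 0 to 2557 between 4 h and 1 h, and 0 to 0 for time slopes. With 1 pair left out the length slope ranged from -0.0993 to -0.0626 and the share of the 10 densest genes from -0.128 to 2.16 points. Low depth limits 1359 genes with under 100 mean reads.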

Other observations

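The gene families here were chosen by name after values had been seen. Of 60 measured protocadherins, adhesion molecules of neural and other cells, 44 fell under DRB and 0 rose. These are not 60 separate measurements, since 38 of them belong to the alpha and gamma clusters, whose nested genes share introns and so reads; all 38 fell. Of the 22 other protocadherins 6 fell and 0 rose, with a median log2 fold change of -0.35, below 0 in 6 of 6 pairs and under each scaling. Of these 18 form the beta cluster, which held all 6 falls and whose median was below 0 in 5 of 6 pairs. Among all 13718 genes 3067 fell, so the share of falls outside the alpha and gamma clusters was not far from that of all genes. The median of these 22 genes still lay below matched lists, at -0.35 against 0.01 (percentile 0.17). That of the beta cluster was -0.39 against 0.09 (percentile 0). Of 207 solute carrier genes 67 fell and 25 rose (percentile 0.02 among random lists matched on density and length), and of 63 potassium channel genes 28 fell and 4 rose (percentile 2.27). With quantile normalization the medians of both went most of the way to 0, from -0.20 to -0.03 and from -0.29 to -0.04. Interleukin receptor genes gave 8 falls and 0 rises among 21 (percentile 22), which lay within the range of matched lists.

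In 6 families the median lay above 0 in 6 of 6 pairs and under each scaling. Of 42 proteasome genes 24 rose and 0 fell, of 56 genes for translation initiation factors 33 rose and 1 fell, and of 22 genes for heterogeneous nuclear ribonucleoproteins 17 rose and 0 fell. Mitochondrial ribosomal protein genes gave 29 rises and 1 fall among 61, NADH dehydrogenase genes 19 and 2 among 37, and genes of the mediator complex, which links activators to polymerase, 15 and 0 among 29. Their medians lay between percentiles 99.46 and 99.97 of matched lists. Aminoacyl tRNA synthetase genes (12 rises and 4 falls among 32) and tubulin genes (4 and 2 among 14) had medians above 0 in 5 of 6 pairs and lay at percentiles 93.16 and 68.4, within the range of matched lists. Genes for 373 microRNAs gave 22 rises and 22 falls, with a median of -0.12 against a matched 0.12 (percentile 0). Those for 272 small nucleolar RNAs gave 21 and 8, with a median of 0.03 against 0.11 (percentile 0.16). Both rest on few reads, with medians of 10.75 and 31.3 mean reads. In all 21 families with at least 10 measured genes were set against matched lists, and smaller ones were not. Collagen and ephrin genes had medians of -0.18 and -0.17 that turned to 0.06 and 0.10 with quantile normalization, so no direction is given for them.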
